A study of Mus musculus with 6 samples.

How the data were processed

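Bulk RNA-seq had been done on 6 libraries of macrophages and monocytes sorted by flow cytometry from mouse kidney. Per the labels' protocols, kidneys were digested with collagenase IV and DNase I, red cells were lysed, dead cells were excluded by dye, and cDNA was made from total RNA with the Smart-Seq v4 ultra low input kit before paired-end sequencing with reads of 75 bases. Kits of this kind amplify full-length poly(A) cDNA and do not mark strand, and the reads carry no molecular identifiers, so intervals and floors given here cover counting error only. Each deposited file held raw read counts per gene from the authors, as whole numbers with no normalization. The submitters' processing notes name STAR as the tool and mm10 as the genome build; the STAR version and the gene annotation are not given in the sources used here. Each file had 4 entries that name no gene (unmapped, multimapping, no feature, ambiguous), which stayed out of library sizes and tests. Of all reads, 9.64% to 10.84% were unmapped, 6.4% to 7.88% mapped to several places, 3.48% to 9.16% fell in no gene and 2.54% to 2.92% were ambiguous. Reads that map to several places were not counted, so near-identical genes such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, or Hspa1a and Hspa1b are uncertain as single genes. The unstranded count column was used. The first-read strand column held 49.99% to 50.08% of the stranded counts, and without strand a gene and an overlapping antisense gene cannot be told apart.

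Each file listed 32285 Ensembl gene IDs. Symbols and coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10, which matched 32158 of the IDs. 26 symbols belonged to several IDs, and the ID with the most counts kept the symbol. Total gene counts ran from 12949780 to 13896696 per library, at which 3 counts correspond to 0.198 to 0.255 CPM, counts scaled to a common library size. A count of 0 is given with the upper limit of its 95% Poisson interval where a limit is printed, and a fold against a library at 0 was computed against the floor of 3 counts in that library.

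Libraries were grouped by their labels. The names of several deposited files describe another population than the labels of their samples do. Groups were not changed for this, and samples were never grouped by the values in them. Of the 4 groups, only the MHC-II-high group had replicates, 3 libraries. A chi-square of the counts per degree of freedom was 19.06 between replicates 1 and 2, 154.8 between 1 and 3, and 154 between 2 and 3, so none of these 3 libraries repeated the counts of another. That they are separate samples rests on the labels, since amplified technical repeats can exceed counting error too.

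Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (TMM scaling, one factor of group over all 6 libraries) on the 15016 genes that passed filterByExpr with a minimum count of 10. Benjamini-Hochberg adjustment was applied, with a threshold of 0.05. The 2 residual degrees of freedom come from the MHC-II-high libraries, and each lone library is assumed to vary like them. The common dispersion was 0.406, a biological coefficient of variation of 0.637. Errors beside log2 fold changes are standard errors, and levels are TMM-scaled CPM with the SD over the 3 libraries. Before the data were examined, 26 gene lists were fixed, holding 319 genes, of which 316 matched a symbol (Mx1, Mx2 and Clec7a did not) and 301 were among the genes tested. 15 lists covered functions or cell states, 10 held markers of other cell types, and 1 held the sort gate genes. The state lists were kidney resident macrophage, perivascular resident macrophage, classical monocyte, non-classical monocyte, MHC class II presentation, type I interferon response, inflammatory cytokines and chemokines, lipid-associated macrophage, matrix and repair factors, complement and Fc receptors, lysosome, cholesterol and lipid handling, cell cycle, dissociation and immediate early genes, and glycolysis and hypoxia. The markers were of dendritic cells, neutrophils, B and plasma cells, T and NK cells, eosinophils and mast cells, renal tubule, endothelium, fibroblasts and mesangium, podocytes, and red cells and platelets. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The estimate rests on the 2 residual degrees of freedom of the MHC-II-high libraries, and so on how those libraries differ among themselves. A list that does not pass with it is therefore not shown to be unchanged. The prior count for log2 CPM was 2. Pairs of single libraries have no replicate check and no test. For them, genes at 50 CPM or more in one library and at least 4-fold apart were counted (prior count 1), and each list's median log2 ratio was placed among 10000 random lists matched on expression.

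Named genes followed a rule fixed before the data were examined. It took the sort gate genes, the 12 called genes with the largest log2 fold change in each direction with a mean log2 CPM of at least 4 and all 3 libraries on one side, up to 4 members of each list with the smallest p, and the 12 largest ratios per direction in each single pair. Predicted genes, mitochondrial, ribosomal protein, histone and antigen receptor segment genes were left out of the ranked picks. Other genes are named where the text says they were chosen after their values were seen.

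The analysis was tested on simulated counts over 15016 genes with 200 genes changed. At a true log2 change of 3, the share recovered was 42% for the design against the healthy library, 41% against the MHC-II-low library and 44% against the monocyte library. At a log2 change of 1 it was 3%, 0% and 0%. Among unchanged genes, 17, 7 and 9 were called, beside 42, 41 and 44 changed genes recovered at a log2 change of 3. At a log2 change of 1, 3, 0 and 0 changed genes were recovered. False calls were thus a larger share of the calls than the Benjamini-Hochberg threshold allows in each of the 3 designs. Genes called in the data may likewise hold more false calls than that threshold implies. Camera found the shifted list and not the unshifted list in each of the 3 designs. Simulated genes were drawn independently, whereas the estimated correlation in the data reached 0.949, for complement and Fc receptors. The simulation therefore cannot show how camera's preset correlation performs on lists whose genes move together. The alternatives, all fixed before the data were examined, were RLE size factors, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, the robust form of edgeR, limma-voom, the strand column, a fit of only the groups compared, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.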

Results

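Gene expression was measured by bulk RNA-seq in 6 libraries of cells sorted from kidneys of NZB/W F1 mice, a hybrid strain that develops a lupus-like disease with nephritis. Every sort took live CD45-positive, CD11b-positive cells that lacked CD3, CD5, CD19, Ly6G, NKp46 and SiglecF, which mark T cells, B cells, neutrophils, NK cells and eosinophils. 1 library was labelled as F4/80-high, CD11b-intermediate cells of healthy, young, untreated kidney (here "labelled healthy"). 3 libraries were labelled as F4/80-high, MHC-II-high, CD11b-high macrophages of nephritic kidney ("labelled MHC-II-high", replicates 1 to 3). 1 was labelled as F4/80-high, MHC-II-low, CD11b-high macrophages of nephritic kidney ("labelled MHC-II-low"), and 1 as F4/80-low, MHC-II-low monocytes of nephritic kidney ("labelled monocyte"). The 5 nephritic libraries also carried a poly(I:C) label, a synthetic double-stranded RNA, so disease, age and treatment cannot be separated. The labels name 2 healthy and 4 nephritic mice without saying which mouse gave which library, so p-values measure only the spread between these libraries, which may be technical. Gene counts per library ran from 12949780 to 13896696, over 13636 to 15590 genes with a count.

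The sort gate genes were read first, because they check the labels, and several went against them. Adgre1 (ENSMUSG00000004730, GRCm38 chromosome 17, 57358691 to 57483527), which encodes F4/80, was lowest in the library labelled MHC-II-low, at 255.4 CPM (95% Poisson interval 246.9 to 264), although that gate was F4/80-high. The library labelled monocyte, gated F4/80-low, held 1247 CPM (1229 to 1265), near the 1388 CPM of MHC-II-high replicate 3. H2-Ab1 (chromosome 17, 34257689 to 34269419), an MHC-II beta chain gene, stood at 15160 CPM in replicate 1 and 17130 CPM in replicate 2. It stood at 579.9 CPM in replicate 3 (567.6 to 592.3), close to the 540.6 CPM of the library labelled MHC-II-low. The library labelled monocyte, gated MHC-II-low, held 14610 CPM of H2-Ab1, as did the library labelled healthy. Cd74, the invariant chain of MHC-II, followed the same division, with 5275 CPM in replicate 3 and 4263 CPM in the library labelled MHC-II-low against 51060 to 61630 CPM elsewhere. Itgam (chromosome 7, 128062640 to 128118491), which encodes CD11b, was at 123 CPM in the library labelled monocyte and at 895.1 to 1479 CPM in the other 5.

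Genes of the lineage markers that the gate excluded were also uneven. Ncr1, which encodes NKp46, reached 222.3 CPM (214.4 to 230.4) in the library labelled MHC-II-low and 10.27 CPM in replicate 3. It had 0 counts in replicates 1 and 2 and in the library labelled healthy, with upper limits of the interval at 0.2866, 0.3138 and 0.2912 CPM. Cd3e was highest in the library labelled MHC-II-low (43.44 CPM), as was Cd19 (12.08 CPM). Cd5 was highest in replicate 3 (16.15 CPM) and Siglecf in the library labelled monocyte (7.909 CPM), and Ly6g stayed at or below 0.81 CPM in every library. Ptprc, which encodes CD45, ran from 804.6 to 1559 CPM. The deposited files of replicate 3, of the library labelled MHC-II-low and of the one labelled monocyte are named for low macrophages, for monocytes and for macrophages, and the file of the library labelled healthy is named like those of replicates 1 and 2. So every direction given here holds for libraries as labelled, and a label does not vouch for the population.

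**Figure D1:**
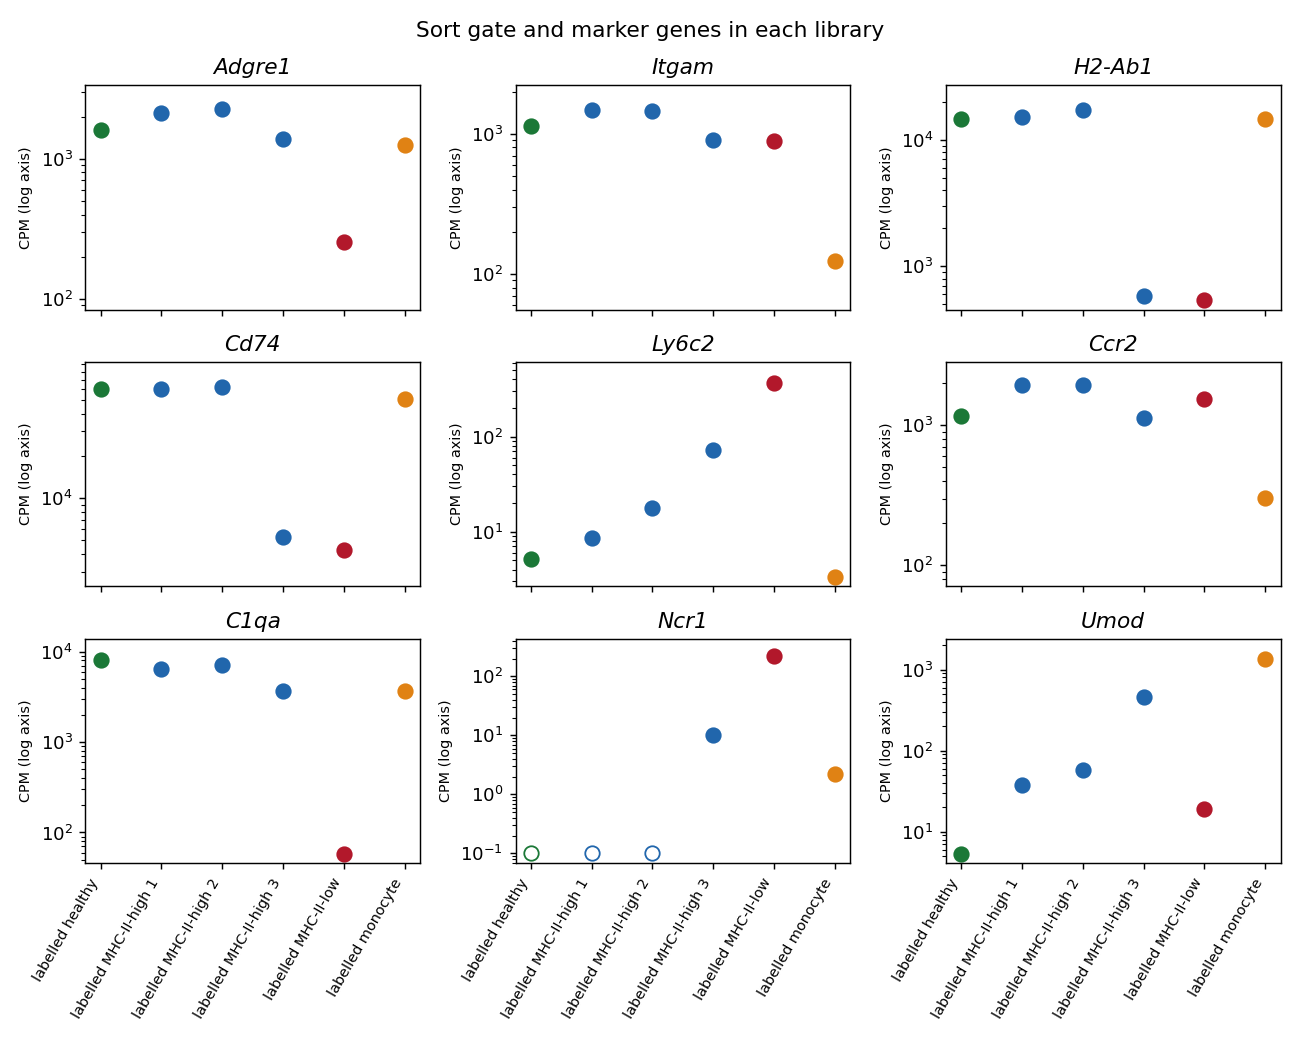
Level of 9 gate and marker genes in each of the 6 libraries, as TMM-scaled CPM on a log axis, with 1 point per library coloured by its label and open points, drawn at 0.1, for a count of 0. Adgre1 was lowest in the library labelled MHC-II-low (255.4 CPM), and H2-Ab1 in replicate 3 (579.9 CPM) lay beside that library (540.6 CPM) rather than beside replicates 1 and 2.

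Across genes, which are not independent replicates, replicates 1 and 2 of the MHC-II-high group resembled the library labelled healthy about as closely as each other. Pearson's r of log2 CPM was 0.952 between replicates 1 and 2, and 0.948 and 0.952 between them and the library labelled healthy. Replicate 3 lay farther off, at 0.889 and 0.898. Of genes at 50 CPM or more, 1 was at least 4-fold apart between replicates 1 and 2, 107 between 1 and 3, and 112 between 2 and 3. The same count was 11 and 10 between the library labelled healthy and replicates 1 and 2. The libraries labelled MHC-II-low and monocyte were the least alike pair, with r = 0.742.

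**Figure D2:**
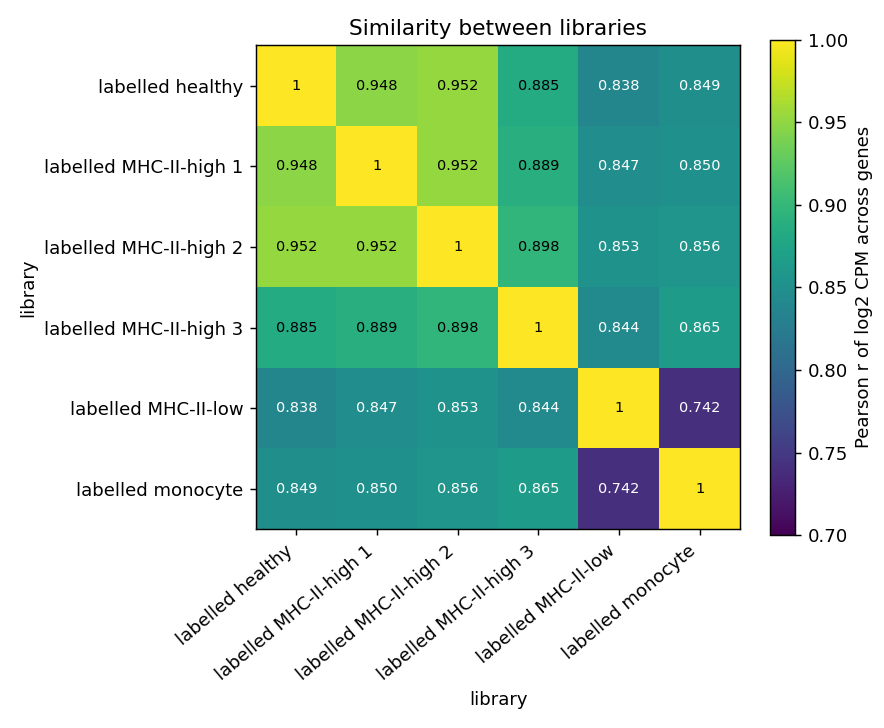
Pearson's r of log2 CPM across genes for every pair of the 6 libraries, with the libraries by label on both axes. The library labelled healthy correlated with replicates 1 and 2 at 0.948 and 0.952, and replicate 3 with them at 0.889 and 0.898.

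The comparison of the libraries labelled MHC-II-high with the one labelled MHC-II-low asks how nephritic macrophages that differ in MHC-II differ otherwise. 11 of 16 kidney resident macrophage genes and 4 of 15 complement and Fc receptor genes were higher in the 3 libraries labelled MHC-II-high, and 5 of 12 T and NK cell genes were lower. With an estimated correlation these lists had adjusted p = 0.813, adjusted p = 0.834 and adjusted p = 0.813. Without replicate 1 or 2 each of the 3 counts was 0, and without replicate 3 they were 16, 12 and 12. The C1q genes are on both the resident and the complement list, so the counts of those lists are not independent. C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187), a chain of complement C1q, was at 6883 ± 2396 CPM (SD, n = 3) against 48.08 CPM, a log2 difference of 7.16 ± 0.80 (adjusted p = 0.0229). Fcrls (chromosome 3, 87250758 to 87263738), an Fc receptor-like gene of tissue macrophages, was at 192.4 ± 31.33 CPM and had 0 counts in the lone library, at least 871-fold higher. Klrb1c (chromosome 6, 128778485 to 128789215), the NK1.1 receptor gene, was at 167.2 CPM in the lone library against 4.874 ± 1.074 CPM, a log2 difference of -5.10 ± 0.31 (adjusted p = 0.00892). In all, 338 of 15016 genes passed, 119 higher and 219 lower in the MHC-II-high group, each with all 3 libraries on the same side. In the simulation of this design, false calls exceeded the share that the threshold allows, so these genes may hold more false calls than it implies.

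Among the 12 largest differences upward, Ptprm, Fblim1, Tpbgl, Neurl1a, Klhl13 and Myh10 had 0 counts in the lone library and were at least 90-fold (Myh10) to at least 197-fold (Ptprm) higher. Col14a1, a fibril-associated collagen, was higher by 9.14 ± 0.80 on the log2 scale. Pf4, a chemokine of platelets and some macrophages, was higher by 8.68 ± 0.63, the chemokine Ccl8 by 7.47 ± 1.15, and the organic anion carrier Slco2b1 by 7.09 ± 0.55. The 12 largest in the other direction were led by Sh2d2a, an adaptor of T and NK cells, at 100.1 CPM in the lone library and 0 counts in every other library. Cd7 differed by -7.97 ± 0.77 and Il2rb, a receptor chain for interleukin-2 and interleukin-15, by -7.97 ± 0.94. Nkg7, a granule protein of cytotoxic cells, differed by -7.06 ± 1.06, the protease gene Gzmb by -6.62 ± 0.85 and the chemokine Ccl5 by -4.96 ± 0.71. Cd3g, Ctsw, Cd2, Gpc1 and Ms4a4b completed them, at log2 differences of -6.68, -6.58, -6.23, -4.58 and -4.08.

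Of the kidney resident macrophage list, 11 of 16 members were higher (15 when adjusted over the list alone) and 0 lower. They included Ms4a7 by 5.71 ± 0.49, Itga9 by 4.88 ± 0.44 and Ptgs1 by 3.09 ± 0.28 on the log2 scale. The list passed with camera (adjusted p = 8.7e-12), and had adjusted p = 0.813 with an estimated correlation. Of the perivascular list, 4 of 11 were higher (6 adjusted over the list alone), among them Gas6, a bridging ligand for dying cells, and Mrc1, the mannose receptor. F13a1, which monocytes also make, was lower by a log2 difference of -1.95 ± 0.24. This list had adjusted p = 0.000731, and adjusted p = 0.813 with an estimated correlation. Of complement and Fc receptors, 4 of 15 were higher (5 adjusted over the list alone), namely C1qa, C1qb, C1qc and the C3a receptor C3ar1 (adjusted p = 0.000276, and adjusted p = 0.834 with an estimated correlation). Of the lysosome list, Hexb passed, at 1428 ± 277 CPM against 240.5 CPM (5 of 18 adjusted over the list alone). The list had adjusted p = 4.15e-05, and adjusted p = 0.813 with an estimated correlation. The C1q genes, Hexb and the sort gate gene Adgre1 are also on the resident list, so these list results overlap.

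3 members of the monocyte lists were lower in the libraries labelled MHC-II-high. 1 of 11 classical monocyte members passed (8 adjusted over the list alone), the proteoglycan Vcan at -5.82 ± 0.56, and 2 of 14 non-classical members (11 adjusted over the list alone), Adgre4 at -2.19 ± 0.25 and Eno3 at -3.28 ± 0.51. These lists had adjusted p = 0.00162 and 2.6e-05, and both had adjusted p = 0.813 with an estimated correlation. Of T and NK cell markers, 5 of 12 were lower (11 adjusted over the list alone), with adjusted p = 4.17e-05 and, with an estimated correlation, adjusted p = 0.813. The median of the T and NK cell list was -5.75, and -10.00 without replicate 3. The B and plasma cell list did not pass (adjusted p = 0.198). Of its members Mzb1 and Cd79a were lower and Ighm higher in the MHC-II-high group, and Jchain, at 1842 CPM in the lone library against 74.46 ± 124.5 CPM, did not pass.

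Of the MHC class II list, 0 of 10 members passed, with H2-Eb1 at 9423 ± 7747 CPM against 282.5 CPM, because replicate 3 held 499.8 CPM. Without replicate 3, 9 of the 10 passed. The list's camera test passed at adjusted p = 0.0233, with adjusted p = 0.834 with an estimated correlation, and did not pass without replicate 1 (0.0668) or replicate 2 (0.0901). In the lipid-associated list, Cd63, the lipid receptor Trem2 and the receptor kinase Axl were higher and the protease inhibitor gene Cst7, also known from NK cells, was lower (3 and 1 of 15, and 6 and 5 adjusted over the list alone). In the cytokine list, the chemokines Ccl8 and Cxcl16 were higher, and Il1rn, Osm and Ccl5 lower (4 and 6 of 19 adjusted over the list alone). Il1rn, the interleukin-1 receptor antagonist gene, stood at 50.99 ± 9.073 CPM against 528.4 CPM. Members of other lists also passed, with Cxcl10, Thbs1, Timp1 and the dendritic cell gene Flt3 lower and Abca1, Cadm1 and the sort gate gene Adgre1 higher.

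The cell cycle list was higher by camera (adjusted p = 8.13e-06), and the neutrophil, glycolysis and hypoxia, and dissociation lists were lower (each adjusted p = 0.0071). None of these lists had a member past the threshold over all genes, and with an estimated correlation they had adjusted p = 0.813, 0.813, 0.834 and 0.85. The dissociation list had a median of -0.59, and without replicate 3 of -0.35, where it did not pass (0.115). The interferon list passed without replicate 3 (0.00744). Lists that did not pass were interferon response (adjusted p = 0.587), cytokines (0.587), lipid-associated (0.523), matrix (0.984), cholesterol (0.7), dendritic cell (0.409), eosinophil and mast cell (0.587), renal tubule (0.587), endothelium (0.791), fibroblast (0.826), podocyte (0.905), red cell and platelet (0.984) and sort gate (0.984). The count of 338 rests on the test and on each replicate. With limma-voom it was 0 (2921 genes at an unadjusted p under 0.05), with DESeq2 1271, and without replicate 1, 2 or 3 it was 0, 1 or 2132.

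**Figure D3:**
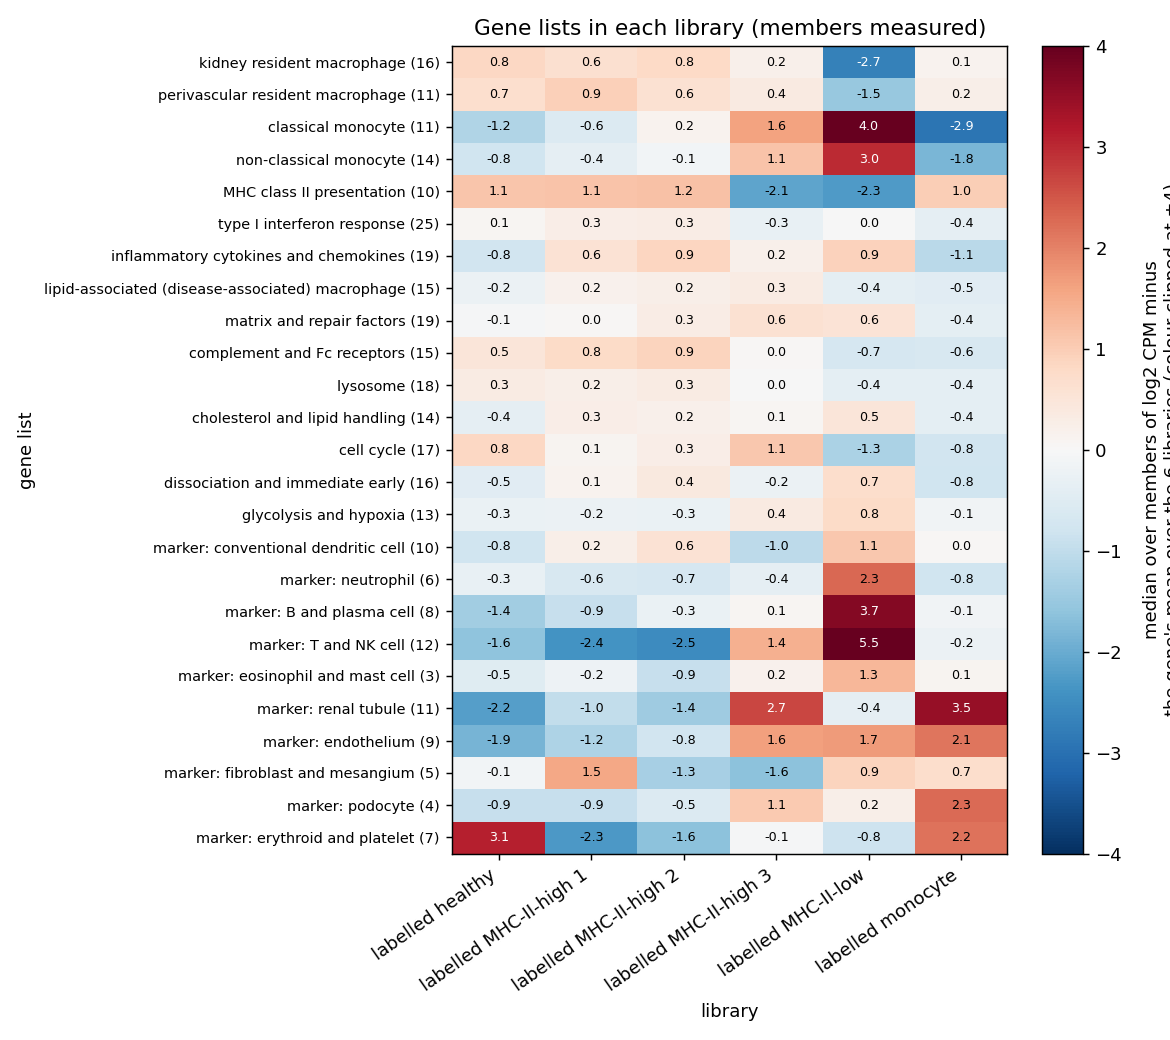
Median over the measured members of each fixed gene list of log2 CPM minus the gene's mean over the 6 libraries, with lists down the side (members measured in brackets) and libraries by label across. The T and NK cell list reached 5.52 in the library labelled MHC-II-low, and the renal tubule list 2.66 in MHC-II-high replicate 3 and 3.49 in the library labelled monocyte.

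The comparison of the libraries labelled MHC-II-high with the one labelled healthy asks how macrophages of nephritic kidney differ from those of young healthy kidney. No gene passed in edgeR's quasi-likelihood test (327 at an unadjusted p under 0.05, 186 of them higher). Inflammatory mediators stood higher as a list. 18 of 19 members had a positive log2 difference, with a median of 1.16 (SD 2.02). The chemokine Ccl4 was at 278.4 ± 67.64 CPM (n = 3) against 119.8 CPM, and the cytokine Tnf at 38.8 ± 7.592 against 16.11 CPM. The list passed with camera (adjusted p = 5.73e-06), with adjusted p = 0.951 with an estimated correlation.

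The dissociation and immediate early list was higher, with 14 of 16 members positive and a median of 0.83 (adjusted p = 0.00163, and adjusted p = 0.951 with an estimated correlation). Atf3, a stress-induced transcription factor, was at 191 ± 51.01 CPM against 68.69 CPM, and Fos at 1479 ± 499.8 against 628.2 CPM. These genes also respond to enzymatic dissociation of tissue. The classical monocyte list was higher in all 11 members (median 2.67, adjusted p = 0.00648) and the non-classical list in 13 of 14 (median 1.30, adjusted p = 0.0127), and both had adjusted p = 0.951 with an estimated correlation. Without replicate 3 these medians were 1.29 and 0.47. Markers of other cells moved with replicate 3 too. T and NK cell markers had a median of 3.13 with it, where the list did not pass, and -0.30 without it, where it passed as lower (0.0388). Renal tubule markers had medians of 4.64 and 0.71 and passed in neither fit. Replicate 3 held the highest level of the 3 for Fn1 (147.6 CPM against 15.08 CPM in the library labelled healthy) and Cd300e (173 against 10.74 CPM). The cholesterol and lipid list was higher in 12 of 14 (median 0.54, adjusted p = 0.00697, and adjusted p = 0.951 with an estimated correlation), with the lipase Lpl at 356.5 ± 86.43 CPM against 204.6 CPM. The cell cycle list was lower, with 3 of 17 members positive and a median of -0.32 (adjusted p = 0.0127, and adjusted p = 0.971 with an estimated correlation). Its median was -0.21 without replicate 1 and -0.75 without replicate 3, and it did not pass without replicate 2 (0.0671), as was the case for the cholesterol list (0.0671).

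Haemoglobin and other red cell genes were lower, with 6 of 7 members of the red cell and platelet list negative and a median of -4.28 (adjusted p = 0.000137, and adjusted p = 0.951 with an estimated correlation). Hba-a1 was at 5.022 ± 4.747 CPM against 117.2 CPM in the library labelled healthy. For members of the lists, 0 passed over all genes. Adjusted over the list alone, 5 red cell genes were lower and 2 non-classical monocyte genes higher. Renal tubule markers ran from a median of -2.20 in the library labelled healthy to 2.66 in replicate 3, on the scale of the plot of list levels.

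Lists that did not pass were resident macrophage (adjusted p = 0.0537), perivascular (0.811), MHC class II (0.196), interferon response (0.981), lipid-associated (0.811), matrix (0.386), complement (0.876), lysosome (0.306), glycolysis (0.383), dendritic cell (0.894), neutrophil (0.372), B and plasma cell (0.308), T and NK cell (0.758), eosinophil and mast cell (0.981), renal tubule (0.0896), endothelium (0.161), fibroblast (0.894), podocyte (0.447) and sort gate (0.876). The resident list passed without each replicate in turn (0.0477, 0.0396 and 0.0206) and was lower. The renal tubule list passed as higher without replicate 1 (0.0477) or 2 (0.0396), and the endothelium list without replicate 1 (0.0449). The interferon list, whose genes poly(I:C) can induce, had 15 of 25 members positive and a median of 0.05, with Stat1 at 560 ± 113.9 CPM against 401.9 CPM. The MHC class II median was -0.39 with replicate 3 and 0.06 without it.

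Limma-voom called 0 genes and DESeq2 65. Without replicate 3, a replicate whose gate genes go against its label, edgeR called 11 genes. The genes named from that fit were chosen after the data were seen, by the same rule. Their standard errors rest only on the spread between the 2 remaining replicates. Cd300e was higher by 3.08 ± 0.31 on the log2 scale, Ccl8 by 2.78 ± 0.30, the complement protease Cfb by 1.51 ± 0.18 and Egr1 by 1.49 ± 0.18. Hba-a1 differed by -5.70 ± 0.38, the stress gene Ddit4 by -5.19 ± 0.38, Hbb-bs by -4.96 ± 0.48, Fkbp5 by -2.24 ± 0.19 and Tsc22d3 by -1.23 ± 0.14. Fkbp5 and Tsc22d3 are known to be induced by glucocorticoids.

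The comparison of the libraries labelled MHC-II-high with the one labelled monocyte asks how the macrophages differ from monocytes of the same disease. No gene passed in edgeR (2577 at an unadjusted p under 0.05), and the largest list differences included monocyte genes that were higher in the libraries labelled as macrophages. The classical monocyte list was positive in 11 of 11 members with a median of 3.78 (adjusted p = 0.00116), and the non-classical list in 11 of 14 with a median of 2.14 (adjusted p = 0.00561). Both had adjusted p = 0.728 with an estimated correlation. Without replicate 3 the non-classical median was 1.19. Ccr2, the chemokine receptor of classical monocytes, was at 1661 ± 467.7 CPM against 300.6 CPM. Adgre4 was at 124.7 ± 25.18 against 2.768 CPM. Treml4 had 0 counts in the library labelled monocyte, beside 85.88 ± 73.89 CPM. The lone library's gate was F4/80-low, and its Adgre1 level did not follow that gate.

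Complement and Fc receptor genes were higher as a list, with 13 of 15 positive (adjusted p = 0.000209, and adjusted p = 0.728 with an estimated correlation), among them properdin, Cfp, at 718.2 ± 124 CPM against 67.82 CPM, and Itgam. Lysosomal genes were positive in 18 of 18 (median 0.50, adjusted p = 1.77e-05, and adjusted p = 0.728 with an estimated correlation), with cathepsin D, Ctsd, at 1394 ± 35.42 against 436.5 CPM. Cytokine and chemokine genes were positive in 18 of 19 (median 1.47, adjusted p = 0.000155, and adjusted p = 0.728 with an estimated correlation), with Ccl2 at 569.9 ± 181.9 against 54.97 CPM and Il1rn at 50.99 ± 9.073 against 0.1318 CPM. The cell cycle list (17 of 17, median 1.26, adjusted p = 0.000454), dissociation list (13 of 16, median 0.86, adjusted p = 0.00561), cholesterol list (12 of 14, median 0.78, adjusted p = 0.0134) and interferon list (20 of 25, median 0.42, adjusted p = 0.0178) were also higher. With an estimated correlation these 4 had adjusted p = 0.728, 0.774, 0.728 and 0.82. The heat shock gene Hspa1b went the other way within the dissociation list, at 220.8 ± 92.03 against 1043 CPM. The interferon list did not pass without replicate 2 (0.0884, median 0.28), and its median without replicate 3 was 0.66.

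The renal tubule list was lower in the libraries labelled MHC-II-high, with 0 of 11 members positive and a median of -1.92 (adjusted p = 0.0164, and adjusted p = 0.774 with an estimated correlation). Its median was -4.87 without replicate 3, which held tubule transcripts itself. Umod, the uromodulin gene of the thick ascending limb, was at 1366 CPM in the library labelled monocyte, 455.4 CPM in replicate 3, and 37.52 and 57.09 CPM in replicates 1 and 2. The red cell and platelet list was lower too (1 of 7 positive, median -3.71, adjusted p = 0.0144, and adjusted p = 0.728 with an estimated correlation). The library labelled monocyte also stood apart in read placement, with 9.16% of reads in no gene against 3.48% to 4.32% in the other 5 libraries, and 0.78% of gene counts mitochondrial against 0.06% to 0.14%.

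Lists that did not pass were resident macrophage (adjusted p = 0.102), perivascular (0.0822), MHC class II (0.556), lipid-associated (0.146), matrix (0.238), glycolysis (0.679), dendritic cell (1), neutrophil (0.33), B and plasma cell (0.707), T and NK cell (0.863), eosinophil and mast cell (0.707), endothelium (0.328), fibroblast (0.829), podocyte (0.238) and sort gate (0.556). Without replicate 3 the resident (0.00207), perivascular (0.00984), lipid-associated (0.00984) and MHC class II (0.0256) lists passed as higher and the T and NK cell list (0.00984) as lower. Mmp13, a collagenase, stood at 19.17 ± 14.69 CPM against 729.4 CPM, and Mmp14, a membrane protease, at 295 ± 30.82 against 26.36 CPM. The test gave 0 genes with limma-voom and 721 with DESeq2, 34 with no filter and 2588 without replicate 3. In that last fit, by the same rule applied after the data were seen, the chemokine Cxcl13 (at least 276-fold), Treml4 (at least 218-fold) and the kinase gene Ikbke (at least 207-fold) led the genes higher in replicates 1 and 2. The genes lower there included the tubule genes Klk1 at -6.82 ± 0.33, Egf at -6.41 ± 0.44 and Aqp2 at -5.70 ± 0.63, and 11 of 11 tubule markers passed.

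The last comparisons set the 3 single libraries against each other, with no replicate check and no test. Between the libraries labelled healthy and MHC-II-low, 450 genes were at least 4-fold apart, 170 higher in the first and 280 in the second. The first side was led by Fcrls (201.9 CPM against 0 counts, at least 914-fold) and Mmp13 (98.53 CPM against 0 counts, at least 446-fold), followed by Tpbgl and Col14a1. Its 12 largest ratios also held Mgl2, a lectin of tissue macrophages (437.5 against 0.7364 CPM), Vcam1 (458.7 against 2.872 CPM) and the 3 C1q genes. The second side was led by the granzyme gene Gzma (730.2 CPM against 0 counts, at least 3080-fold), Il2rb, Cd7, Gimap4 and the perforin gene Prf1 (243.4 CPM against 0 counts, at least 1030-fold). The resident macrophage list's median log2 ratio was 3.98 (SD 2.09), above all 10000 matched random lists (percentile 100), the classical monocyte list's -5.67 (SD 2.70, percentile 0) and the T and NK cell list's -7.37 (SD 3.10, percentile 0).

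Between the libraries labelled MHC-II-low and monocyte, 699 genes were at least 4-fold apart, 402 higher in the first and 297 in the second. Haptoglobin, Hp (831.9 CPM), Chil1 (747.5 CPM), Treml4 (513.6 CPM), a receptor of non-classical monocytes, and Slpi (328.9 CPM) had 0 counts in the library labelled monocyte, at least 1660-fold apart for Slpi to at least 4210-fold for Hp. Fibronectin, Fn1, was at 773 against 0.2636 CPM. On the other side, Mmp13 (729.4 CPM) had 0 counts in the library labelled MHC-II-low, and Mgl2, Pf4 and Slco2b1 were at 905.1, 244.4 and 582.7 CPM against 0.7364, 0.6627 and 2.725 CPM. The classical monocyte list was higher in the library labelled MHC-II-low in all 11 members (median log2 ratio 7.20, SD 3.78, percentile 100) and the resident macrophage list lower in 15 of 16 (median -2.89, SD 2.34, percentile 0). The MHC class II list was higher in the library labelled monocyte in all 10 members (median -3.45, SD 1.56, percentile 0), whereas both gates were MHC-II-low.

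Between the libraries labelled healthy and monocyte, 206 genes were at least 4-fold apart, 42 higher in the first and 164 in the second. The first side held Jaml, an adhesion molecule of leukocytes (57.32 against 0.1318 CPM, from 2 counts), Spon1 (89.21 against 1.318 CPM), the complement gene C4b (102.8 against 3.955 CPM), Cfp and Itgam. The second side was led by genes of renal tubule and collecting duct with 0 counts in the library labelled healthy, among them Egf (798.4 CPM, at least 3370-fold), the water channel Aqp2 (251.6 CPM, at least 1060-fold) and the potassium channel Kcnj1 (165.8 CPM, at least 700-fold). The renal tubule list's median log2 ratio was -6.06 (SD 2.82, percentile 0) and the cell cycle list's 1.57 (SD 0.83, percentile 100), while the MHC class II list's was 0.19 (SD 0.52, percentile 15.44) and the resident list's 0.78 (SD 1.14, percentile 99.85).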

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

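Every alternative below was planned, and the cause of a change was not tested. All fits without a replicate hold equally many libraries, so their number does not explain why the calls differ with the replicate left out. Against the library labelled healthy, the number of genes called went from 0 to 65 with DESeq2 and ran from 0 to 11 when each replicate was left out. Against MHC-II-low it went from 338 to 1271 with DESeq2 and to 0 with limma-voom, and from 0 to 2132 over the replicates left out. All 338 genes were among the 2132, with the same sign, and between 257 and 331 of them were shared with the calls under DESeq2, the robust fit, RLE, the strand column or either filter. Against monocyte it went from 0 to 34 with no filter, 5 with the stricter filter, 721 with DESeq2 and 36 with the robust fit, and from 0 to 2588 over the replicates left out. The number of lists called, 7, 12 and 11, went to 0 in all 3 comparisons with camera's estimated correlation and with fry. 3 lists turned direction and passed without replicate 3. Other lists that turned when a replicate was left out passed neither before nor after. Over the replicates left out it ran from 0.0388 to 0.333 for T and NK cells against healthy, 0.0256 to 0.315 for MHC class II against monocyte and 0.00984 to 0.479 for T and NK cells against monocyte. Genes at least 4-fold apart between single libraries numbered 884, 1734 and 1056 with a minimum of 10 CPM, for healthy with monocyte, MHC-II-low with monocyte and healthy with MHC-II-low. With a minimum of 100 CPM the first and second numbered 96 and 433. On the 1000 genes with the highest variance, the correlation of the libraries labelled MHC-II-low and monocyte turned to -0.408, and replicate 3's correlation with replicates 1 and 2 lay -0.182 from that of the library labelled healthy, against -0.056 over all genes. With plain library sizes the library labelled monocyte ranked 2 for H2-Aa and 1 for H2-Ab1, and with the strand column 3 for H2-Ab1, each from 4. The other counts and ranks stayed within 1.5 times of the values reported. No paired analysis was possible because only the MHC-II-high libraries carry replicate numbers. Depth, alike in all 6 libraries, limits genes under the floor of 3 counts. The 2 residual degrees of freedom limit every test, and fits without a replicate leave only 1. The spread in those fits rests on the 2 MHC-II-high libraries that remain.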

Other observations

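The tests of sequencing depth and of cells diluting replicate 3 were chosen only after the result was seen, and the others were written before the tests were run. Some genes of the tubule and NK cell tests had also come up among the largest differences, as said below. Some list genes stood apart in single libraries. Spp1, which encodes osteopontin, was at 2749 CPM in MHC-II-high replicate 3 and at 385.3 to 852.1 CPM in the other 5 libraries, and Tmem119, a marker of some tissue macrophages, was at 329.6 CPM there, 125.1 CPM in the library labelled healthy and 8.174 to 61.25 CPM elsewhere. The proliferation genes Mki67 and Stmn1 were highest in replicate 3 (31.14 and 58.86 CPM) and in the library labelled healthy (28.34 and 58.34 CPM), and replicates 1 and 2 held 18.57 and 17.78 CPM of Mki67. Immunoglobulin kappa, Igkc, was at 7280 CPM in the library labelled MHC-II-low, 966.6 CPM in replicate 3 and 6.371 to 102.4 CPM in the others. These genes were picked out after their values were seen, and beyond the tests of the 3 comparisons no test was made of these patterns.

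Several libraries did not carry the gate genes their labels name. The values exclude sequencing depth as a cause, since the highest total was 1.07 times the lowest. They argue against dilution of replicate 3 by cells that lack both resident and MHC-II genes, which would lower both alike. Against the mean of replicates 1 and 2 the resident list's median log2 ratio was -0.64 (SD 0.91) and that of 4 MHC-II genes -4.8 (SD 0.64), a difference of 4.15. Cells with resident genes but little MHC-II could give such values too, so the test cannot exclude dilution by them. What mislabelling requires was present for all 4 libraries it was tested on, though not without values on the other side. Adgre1 in the library labelled monocyte was 4.88 times that of the lowest library labelled F4/80-high, the one labelled MHC-II-low, but below the 1388 to 2261 CPM of the other 4. Adgre1 in the library labelled MHC-II-low had rank 1 from the lowest. That library's MHC-II genes, at a median log2 ratio of -4.38 to the mean of replicates 1 to 3, were low as labelled. The monocyte gate was MHC-II-low too, so this value does not tell those gates apart. Replicate 3 correlated with replicates 1 and 2 at 0.894 against 0.95 for the library labelled healthy. That library lay 0.989 of the way from the least alike pair to replicates 1 and 2. Its Itgam, at 1147 CPM, was below their 1479 and 1450 CPM, as its CD11b-intermediate label implies. Yet that level was above the 903.3 CPM of replicate 3 and the 895.1 CPM of the library labelled MHC-II-low, both gated CD11b-high. The tests of the libraries labelled monocyte and MHC-II-low both rest on Adgre1. Once the library labelled MHC-II-low was the lowest, the library labelled monocyte had to meet its test, so these are not independent. The tests of replicate 3 and of the library labelled healthy both use the latter's correlation, so they are not independent either. A small effect of disease would meet the last test too. A candidate explanation is therefore that labels and libraries were mismatched for several samples, in which case the comparison with the library labelled healthy may set like against like, and no library was assigned to another population here. A small effect of disease on these macrophages, and mRNA levels that depart from surface protein, stay open and untested.

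Renal tubule transcripts stood high in the library labelled monocyte and in replicate 3, with Gpx3 at 4666 and 3746 CPM, Aldob at 1193 and 933.2 CPM and Umod at 1366 and 455.4 CPM. Of 10 further tubule genes, fixed before the test, 10 were higher in both libraries than in each of the other 4, which is what RNA of tubule cells in the sorted sample requires. 0 of the 10 was in another fixed list, but most had counts in every library, Ass1 was only 1.04 times the highest other library, and Fxyd2 was at 78.5 to 104 CPM in the other 4 against 1050 and 400 CPM. Calb1, among the 10, also had the largest difference downward against the library labelled monocyte in the fit without replicate 3, so it is not fresh support. The CD45 gate would remove tubule cells, so with RNA of renal tubule cells in the sorted sample at 10 of 10, free RNA, attached fragments or material taken up by macrophages may be the source, and these were not separated.

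NK cell transcripts stood high in the library labelled MHC-II-low, with Gzma at 730.2 CPM, Nkg7 at 544.7 CPM and Il2rb at 359.5 CPM. Of 8 further NK genes, fixed before the test, 7 were at least 10 times the highest other library, as RNA of NK cells in the sorted sample requires, and Klrk1 was 9.42 times. Prf1 is also named above among the largest ratios between single libraries. Tbx21 was among the largest differences from this library without replicate 3, so neither gene is fresh support. The gate excluded NKp46 and CD3, yet Ncr1, at 222.3 CPM, and Cd3e, at 43.44 CPM, were also highest there. NK cells that passed the gate may thus be a source, beside Ly6c2 at 363.6 CPM and Lyz2 at 22280 CPM, which monocytes express. Lyz2 was chosen after its values were seen. It was the gene with the most counts in replicate 3 too, at 1.57% of gene counts against 2.18% in the library labelled MHC-II-low. Its level thus does not set that library apart from replicate 3 as monocytes. A myeloid population expressing the NK cell genes was not tested.

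Fkbp5, Tsc22d3 and Ddit4 were higher in the library labelled healthy than in replicates 1 and 2, at 341, 1080 and 107 CPM against at most 78.5, 468 and 3.42 CPM. The hypothesis that genes induced by glucocorticoids are higher there as a group came from the genes called without replicate 3 and was tested on 10 further such genes fixed before their values were seen. Only 2 of the 10, Klf9 and Zbtb16, were at least 1.5 times higher than in both replicates, with Per1 at 1.49 times. Sgk1, Mt2, Txnip and Mt1 were at 1.28, 1.2, 1.11 and 1.07 times the higher replicate, and Errfi1, Cdkn1a and Pdk4 at 0.824, 0.693 and 0 times. The group thus did not rise together by that factor. Most of its genes were above the higher replicate, but with a lone library such small ratios cannot be told from the spread between libraries.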
